A study of Mus musculus with 32 samples.

How the data were processed

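Messenger RNA was sequenced from gastrocnemius muscle of young male mice, taken 7 or 28 days after surgery. Mice had sham surgery or a complete spinal cord injury (SCI), and injured mice received either vehicle or boldine, an alkaloid known to block connexin and pannexin hemichannels. Per the labels, RNA came from about 20 mg of muscle cut to hold equal parts of the medial and lateral heads. It was isolated with the miRNeasy kit, and 1 μg per sample went into NEBNext Ultra libraries, a kit that does not keep the strand of the transcript. The deposited values are raw read counts per gene, whole numbers under Ensembl gene identifiers, which the authors made from reads checked with FastQC, trimmed with Trim Galore and cutadapt, and aligned with STAR to mm10. Versions of these tools, the counting step, its strand setting and the gene annotation are not given in the sources used here.

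The table held 55487 gene identifiers in 32 libraries, and 25611 identifiers had no count in any library. Symbols and coordinates came from the GENCODE M21 annotation of mm10, which named 55227 identifiers. The 260 others held 0.0189% of all counts. Where identifiers shared a symbol, the most counted one kept it, which set 116 aside for naming. No library was identical to another. Library totals lay between 9935424 and 14132960 counts, and 3 counts in a library, the limit that a count of 0 allows, stand for 0.233 CPM in sham 7-day library 3, for example. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

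Each library was placed in 1 of 6 groups by its time, surgery and treatment labels, and the labels name no further batch. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 14955 genes. Libraries were scaled by the trimmed mean of M values (TMM), and one quasi-likelihood model of edgeR with a mean per group was fitted to all 32 libraries in R 4.3.3. Comparisons were SCI with vehicle against sham, SCI with boldine against SCI with vehicle, and SCI with boldine against sham, each at 7 and at 28 days. The difference between days was tested for the SCI effect and for the boldine effect. P-values were two-sided and adjusted by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic, an approximation. Fold changes carry the default prior count of edgeR, and log2 CPM values a prior count of 2. Levels are CPM of TMM-scaled libraries, given as mean ± SD. The p-values measure the spread between these samples, since the labels do not say how the animals were housed, operated or dosed.

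The groups, comparisons, 32 gene lists, naming rule and all alternatives but one were chosen before the data were examined. The naming rule took, for SCI against sham and boldine against vehicle, the 6 largest rises and 6 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM over both groups, no overlap of CPM between the groups and no predicted-gene symbol. For boldine against sham and for differences between days it took 3 in each direction, without the overlap condition for the latter, and where nothing was called the 3 smallest p-values in each direction. Of each list described it took the 3 members with the smallest p-values, not all of which are named. Members that went against the rest of their list, and the few boldine calls outside the rule, were chosen after their values were seen. Results for a few genes that the rule takes are not reported here.

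The lists were neuromuscular junction and denervation genes, atrophy-related ubiquitin ligases, proteasome, autophagy and lysosome, slow fibre, fast fibre, developmental muscle, satellite cell, nuclear oxidative phosphorylation (OXPHOS), tricarboxylic acid cycle, fatty acid oxidation, glycolysis, extracellular matrix, fibro-adipogenic progenitor, macrophage, lymphocyte, neutrophil, endothelial, Schwann cell, adipocyte, erythrocyte, hemichannel and purinergic receptor, antioxidant, inflammatory signalling, interferon, glucocorticoid response, circadian clock, cell cycle, endoplasmic reticulum and heat stress, immediate early, mitochondrially encoded, and ribosomal protein genes. All 477 list entries were found in the table, and some genes stand in more than 1 list. Lists were tested against the other genes with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks only whether members move one way on balance. Counts of members adjusted over the list alone are given for some of the lists where they differ from those over all genes. Lists with fewer than 3 measured members were not tested. Where no tool stands beside an adjusted p for a gene, it is from edgeR.

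The pipeline was tested on simulated data in which 200 genes of real libraries were changed 1.5-, 2- or 4-fold. For SCI against sham it recovered 71.6% of 2-fold changes at 7 days and 71.6% at 28 days, over 14619 and 14580 genes. For boldine against vehicle it recovered 73.1% at 7 days and 74.6% at 28 days, over 14539 and 14561 genes. For the differences between days it recovered 56.7% for SCI and 58.2% for boldine, over 14579 and 14568 genes. Of 1.5-fold changes it recovered 44.8% for boldine against vehicle at 7 days and 61.2% at 28 days. For the difference of boldine effects it recovered 26.9% of them. In these 3 simulations 13, 5 and 7 unchanged genes were called. No gene called for boldine against vehicle in the data changed more than 2-fold. A raised OXPHOS list was called and none of the other lists counted with it were. The tricarboxylic acid cycle list, which shares genes with OXPHOS, was left out of that count. Genes were drawn independently of each other in the simulation. It therefore cannot show how often camera calls a list wrongly where the members are correlated.

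Alternatives were size factors of DESeq2 in edgeR, library totals with no scaling factor, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, robust dispersions, no low-count filter, a stricter filter of CPM above 1 in at least 10 libraries, only the libraries of the compared groups, a replicate block, and each library left out in turn. The 28-day SCI boldine library 6 was also counted as vehicle, since its description code carries the letter of the 28-day SCI vehicle libraries. A term for 2 sets of libraries found in the data was added after seeing the data. Up to 100 splits of the samples were drawn per comparison with a fixed seed. Correlations across libraries used 100000 permutations, or exact enumeration below 10 libraries. Figures and correlations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.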

Results

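Gene expression was measured in 32 gastrocnemius muscles to ask how complete spinal cord injury changes muscle transcripts and whether boldine alters that response. At 7 days there were 4 sham, 6 SCI vehicle and 6 SCI boldine libraries, and at 28 days again 4, 6 and 6. Total counts per library ran from 9980885 to 12864837 in sham, from 9935424 to 13040986 in SCI vehicle and from 11402294 to 12885290 in SCI boldine at 7 days. At 28 days they ran from 10655924 to 12405094 in sham, from 11697123 to 14132960 in SCI vehicle and from 10928810 to 12886336 in SCI boldine. The 10 most counted genes held 27.0% ± 1.61 of counts in 7-day sham (SD, n = 4) and 19.0% ± 4.05 in 7-day SCI vehicle (n = 6). The first principal component carried 40.7% of the variance.

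At 7 days after injury the muscle had gained transcripts that sham muscle barely held. Sln, which encodes sarcolipin, a regulator of the calcium pump of the sarcoplasmic reticulum, rose from 1.31 ± 0.428 CPM in sham (n = 4) to 72.2 ± 30.3 CPM in SCI vehicle (n = 6), a log2 fold change of 5.78 ± 0.55 (SE). Krt18, a keratin of intermediate filaments, rose from 0.306 ± 0.117 to 24.1 ± 10.2 CPM, and Mt2, a metal-binding metallothionein, from 2.14 ± 0.56 to 72.0 ± 43.4 CPM. Bdh1, the mitochondrial dehydrogenase that uses the ketone body 3-hydroxybutyrate, fell from 32.4 ± 20.2 to 0.552 ± 0.447 CPM, and Actc1, the cardiac actin of developing muscle, from 207 ± 110 to 5.29 ± 1.66 CPM. Perm1, a muscle regulator of mitochondrial genes, fell from 199 ± 55.0 to 14.7 ± 5.91 CPM, and Ckmt2, the mitochondrial creatine kinase of muscle, from 800 ± 204 to 62.0 ± 19.1 CPM. Other large rises were Ces2c, a carboxylesterase (log2 6.12 ± 0.54), and Ggt6, a gamma-glutamyltransferase (5.45 ± 0.59). Lynx1, which modulates nicotinic acetylcholine receptors (-3.67 ± 0.18), and the secreted factor Ostn (-3.46 ± 0.28) also fell. Cd101, an immunoglobulin-family surface protein, stood at 748 counts over 6 vehicle libraries and 1 count over 4 sham libraries. Over library totals, without TMM scaling, this was a ratio of 479 with a 95% counting interval of 85.7 to 18933. By edgeR its log2 fold change was 7.94 ± 0.90, a smaller ratio. All 12 moved in 6 of 6 vehicle libraries, which the naming rule requires, with adjusted p between 1.6e-07 for Mt2 and 9.3e-16 for Lynx1. In mm10, Sln lies on chromosome 9 from 53850164 to 53854560, Krt18 on chromosome 15 from 102028180 to 102032027, Bdh1 on chromosome 16 from 31422280 to 31458901 and Actc1 on chromosome 2 from 114047282 to 114053548. In total edgeR called 3218 genes higher and 3451 lower, of which 753 and 1027 changed more than 2-fold. With library totals in place of TMM the counts were 7107 higher and 1362 lower, and the median of all genes shifted by 0.37 on the log2 scale, so directions here are relative to that shift. Mt2, Ostn, Ckmt2 and Bdh1 overlap other annotated genes on the opposite strand, so their reads were not fully separable.

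Genes of denervated muscle and of protein breakdown rose at 7 days. Among 20 neuromuscular junction and denervation genes 14 rose and 4 fell, or 14 and 2 with library totals. Gadd45a, a stress gene of denervated fibres, rose from 15.8 ± 2.15 to 302 ± 196 CPM and Chrnb1, a subunit of the acetylcholine receptor, from 29.7 ± 1.09 to 106 ± 15.2 CPM. The 4 that fell were Ache, the esterase that clears acetylcholine, Dach2, a repressor of Myog, and Dok7 and Lrp4, parts of the receptor complex that clusters acetylcholine receptors. Proteasome subunits rose in 31 of 31 measured genes, with Psmd2 from 306 ± 18.2 to 835 ± 180 CPM and Psmd4 from 132 ± 14.1 to 313 ± 66.5 CPM. Of 16 atrophy-related ubiquitin ligase genes 7 rose, or 12 with library totals, among them Trim63 (MuRF1) from 220 ± 56.8 to 754 ± 329 CPM, while the ligase Fbxo40 (-0.87) and the conjugating enzyme Ube2b (-0.45) fell. With library totals only 1 gene of that list fell. In the autophagy and lysosome list 9 of 16 rose, or 10 when adjusted over the list alone, led by Map1lc3a from 118 ± 10.9 to 362 ± 35.2 CPM. The protease Ctsb (-0.64) and the lysosomal regulator Tfeb (-0.66) fell. Ribosomal protein genes rose in 46 of 48, with Rpl3, a core protein of the large subunit, from 36.6 ± 4.13 to 239 ± 78.7 CPM. Against other genes, camera gave an adjusted p of 4.1e-22 for the proteasome (median log2 0.81; adjusted p = 0.18 with an estimated correlation) and of 1.8e-26 for ribosomal proteins (0.64; adjusted p = 0.18 with an estimated correlation). It gave 0.0010 for the junction list (1.48; adjusted p = 0.20 with an estimated correlation), 0.013 for ubiquitin ligases (0.36; adjusted p = 0.20 with an estimated correlation) and 0.0010 for autophagy (0.40; adjusted p = 0.18 with an estimated correlation). With library totals these 5 medians were 1.22, 1.04, 1.89, 0.75 and 0.80, and 13 autophagy and lysosome genes rose. By fry the adjusted p of these 5 lists, in the same order, was 4.1e-08, 7.8e-09, 8.5e-07, 3.0e-06 and 7.8e-09.

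Energy metabolism and contractile genes fell over the same days. Of 45 nuclear OXPHOS genes 44 fell, or 25 with 1 higher with library totals (median -0.63 and then -0.25), among them Ndufs1 of complex I (log2 -1.05 ± 0.08) and Cox7a1 of complex IV (-2.04 ± 0.16). Of 17 tricarboxylic acid cycle genes 16 fell, led by Idh3a (-1.48 ± 0.11), and 10 of 10 mitochondrially encoded genes fell, led by mt-Nd1 (-0.86 ± 0.10) and mt-Co1 (-0.92 ± 0.11). All 13 glycolysis genes fell, with the glycogen synthase Gys1 at -1.15 ± 0.10 and Pgk1 at -1.37 ± 0.12. In fatty acid oxidation 15 of 20 fell, led by the dehydrogenase Acadm (-1.33 ± 0.12) and the lipase Lpl (-1.98 ± 0.23), while Pdk4, which restrains pyruvate use (1.63), the uncoupling protein Ucp3 (1.42) and the carnitine carrier Slc25a20 (0.31) rose. With library totals 4 fell and 5 rose, and the list's median of -0.38 became 0.01. Sham library 2 went against this fall, at a mean of 6.21 log2 CPM against 6.84 to 7.14 in the other sham libraries and 6.26 to 6.55 in SCI vehicle, and without it the median on voom values went from -0.36 to -0.52. Slow fibre genes fell in 11 of 11, led by the light chain Myl3 (-3.16 ± 0.43) and the calcium-binding Casq2 (-1.98 ± 0.27). Sham library 2 stood apart in this list as well, at a mean of 4.89 log2 CPM against 6.79 to 7.37 in the other sham libraries and 2.89 to 5.77 in SCI vehicle, with Myh7 at 89.8 CPM against 549 to 762 CPM. Fast fibre genes fell in 11 of 13, led by the light chains Myl1 (-1.60 ± 0.19) and Mylpf (-1.36 ± 0.19). By camera the adjusted p was 1.3e-24 for OXPHOS (adjusted p = 0.18 with an estimated correlation), 9.4e-15 for the tricarboxylic acid cycle (adjusted p = 0.18 with an estimated correlation) and 9.7e-08 for mitochondrially encoded genes (adjusted p = 0.18 with an estimated correlation). It was 1.1e-09 for glycolysis (adjusted p = 0.18 with an estimated correlation), 0.0061 for fatty acid oxidation (adjusted p = 0.57 with an estimated correlation), 2.0e-04 for slow fibre (adjusted p = 0.35 with an estimated correlation) and 3.2e-06 for fast fibre genes (adjusted p = 0.20 with an estimated correlation). By fry the adjusted p of these lists ran from 5.0e-10 for the tricarboxylic acid cycle and 3.2e-09 for OXPHOS to 3.5e-04 for slow fibre genes and 0.0039 for fatty acid oxidation.

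Markers of other cell types moved as well at 7 days. Extracellular matrix genes fell in 16 of 18, led by the basement membrane collagens Col4a1 (-1.10 ± 0.14) and Col4a2 (-1.12), while Timp1, an inhibitor of matrix proteases, rose by 2.82. Fibro-adipogenic progenitor markers fell in 7 of 10, or 3 with library totals (median -0.54 and then -0.15), led by Cd248 (-2.11 ± 0.25) and Pi16 (-2.07 ± 0.29). Endothelial markers fell in 7 of 9, or 2 with library totals (median -0.54 and then -0.15), with the VEGF receptor Kdr at -1.35 ± 0.20 and Emcn at -1.20 ± 0.17, while Cldn5, a tight junction protein, rose by 0.90. Adipocyte markers fell in 6 of 6, led by Plin1 (-2.49 ± 0.62) and Adipoq (-2.37 ± 0.59). Of 12 macrophage markers 1, the lysosomal Cd68 (1.74 ± 0.46), rose, and the list's median of -0.20 became 0.19 with library totals. Schwann cell markers fell in 3 of 9, among them the myelin genes Pmp22 and Prx, whose calls ended without sham 7-day library 2 (adjusted p 0.055 and 0.26). Of 3 neutrophil markers Csf3r fell (-2.38), a call that ended without sham library 3 (adjusted p 0.46) or SCI vehicle library 2, 3 or 4 (0.069, 0.056 and 0.051). The 5 erythrocyte genes gave 0 calls by edgeR and their median of -0.10 became 0.28 with library totals, and 0 lymphocyte markers passed the filter. The adjusted p by camera was 2.8e-06 for matrix (adjusted p = 0.20 with an estimated correlation), 0.0021 for progenitors (adjusted p = 0.31 with an estimated correlation), 0.013 for endothelium (adjusted p = 0.35 with an estimated correlation) and 0.041 for adipocytes (adjusted p = 0.56 with an estimated correlation). For Schwann cells, neutrophils and macrophages it was 0.22, 0.45 and 0.72. By fry it was 1.7e-06 for matrix, 6.5e-05 for progenitors, 2.5e-04 for endothelium and 0.0073 for adipocytes. Schwann cells, neutrophils and macrophages had 0.10, 0.066 and 0.49 by fry.

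Stress and signalling genes at 7 days included 5 of 8 inflammatory signalling genes that rose, or 7 when adjusted over the list alone and 8 with library totals. Nfkb2, a subunit of NF-kappaB, rose from 14.3 ± 4.16 to 152 ± 73.5 CPM and its partner Relb by 2.23 ± 0.25 (camera 0.0084; adjusted p = 0.31 with an estimated correlation). Antioxidant genes rose in 11 of 15, or 12 when adjusted over the list alone, with Sod1 at 0.78 ± 0.10, while the mitochondrial dismutase Sod2 fell by 0.87 (camera 0.0033; adjusted p = 0.30 with an estimated correlation). By fry inflammatory signalling genes had an adjusted p of 1.5e-04 and antioxidant genes of 3.6e-04. Panx1, the pannexin channel that boldine is known to block, rose from 8.91 ± 2.06 to 35.0 ± 19.3 CPM. Of the other 8 hemichannel and purinergic genes 5 fell over all genes, 1 more rose when adjusted over the list alone, and with library totals none fell and the list's median of -0.37 became 0.02 (camera 0.66). Gja1, which encodes connexin 43, fell (-0.61 ± 0.18), a call that ended with library totals (-0.23). P2rx6 had -0.37 but 0.02 with library totals, and its call ended without sham library 2 or 4 (adjusted p 0.066 and 0.058). Glucocorticoid response genes rose in 5 of 11, led by Mt2 (5.08 ± 0.66) and the cell cycle inhibitor Cdkn1a (2.28 ± 0.34), and Klf9 fell (camera 0.13). With library totals 6 of these genes rose and 0 fell. Circadian genes rose in 3 and fell in 7 of 15, led by Bhlhe41 (-1.23 ± 0.13), with a median of -0.32, but 6 were higher and 3 lower with library totals and the median became 0.06. Immediate early genes rose in 3 of 10, led by Jun (1.36 ± 0.18), and Nr4a1 fell (camera 0.22). Developmental muscle genes rose in 3 of 8, with Mymx, a fusion factor of myoblasts, at 5.05 ± 0.98, while Actc1 fell (camera 0.75). Satellite cell genes rose in 2 and fell in 2 of 7, or 3 when adjusted over the list alone, with Cdh15 at 1.22 ± 0.15 and Myf5 at 1.26 ± 0.24. Their median was -0.26 and their mean 0.09, and with library totals none fell and the median was 0.13. The call of Chodl among them (-0.61) ended without sham library 2 or 3 (adjusted p 0.052 and 0.10). Endoplasmic reticulum and heat stress genes rose in 4 of 11 and fell in 1, or 6 and 0 with library totals, with Hsp90b1 at 0.69 ± 0.13. Of 7 cell cycle genes Ccna2 rose (0.54) and Mcm2 fell (-0.68), the first not without sham library 3 (adjusted p 0.069) and the second not with library totals (-0.30). The 9 interferon genes gave a camera adjusted p of 0.66, and their median of -0.35 became 0.03 with library totals.

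**Figure D1:**
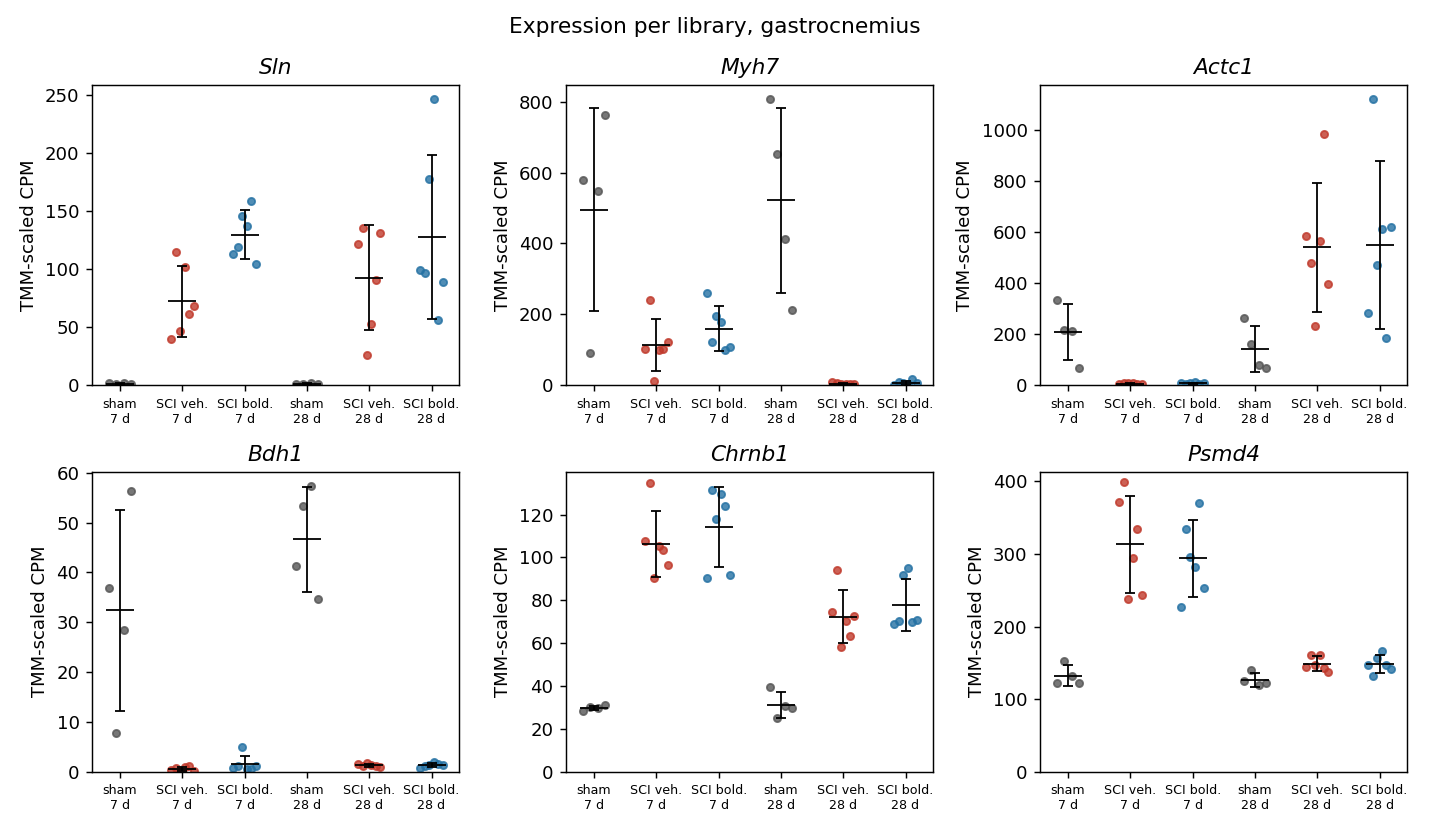
Levels of Sln, Myh7, Actc1, Bdh1, Chrnb1 and Psmd4 in TMM-scaled CPM on the vertical axis, with 1 point per library in the 6 groups and bars for mean ± SD. Sln averaged 1.31 CPM in 7-day sham against 72.2 CPM in 7-day SCI vehicle, and Myh7 averaged 521 CPM in 28-day sham against 4.07 CPM in 28-day SCI vehicle.

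At 28 days after injury genes of the slow contractile apparatus stood far below sham. Myh7, the slow myosin heavy chain, fell from 521 ± 262 CPM in sham (n = 4) to 4.07 ± 2.70 CPM in SCI vehicle (n = 6), a log2 fold change of -6.99 ± 0.66 (SE). Myl2, the slow regulatory light chain, fell from 162 ± 63.0 to 1.64 ± 0.757 CPM, and the slow troponins Tnnc1 (-5.25 ± 0.55) and Tnni1 (-4.07 ± 0.48) and the ketone body enzyme Bdh1 (-5.12 ± 0.44) fell with them. Sln rose from 1.05 ± 0.386 to 92.8 ± 45.1 CPM, and Aldh3a1, an aldehyde dehydrogenase, from 0.372 ± 0.136 to 9.68 ± 4.59 CPM. Runx1, a transcription factor of denervated muscle, rose from 1.82 ± 0.296 to 10.2 ± 3.64 CPM. Other rises were Cyp2e1, a cytochrome P450 (3.07 ± 0.73), Srrm4os (2.64 ± 0.34), an antisense transcript whose reads were not separable from Srrm4 without strand, and Aif1l (2.43 ± 0.53). All 12 moved in 6 of 6 vehicle libraries, which the naming rule requires, with adjusted p between 0.0059 for Cyp2e1 and 3.9e-09 for Sln. The Cyp2e1 call ended in voom with quality weights (adjusted p 0.065). Mhrt, which overlaps Myh7 on the other strand, fell by 6.66 ± 0.61, but without strand its reads were not separable from those of Myh7. In mm10, Myh7 lies on chromosome 14 from 54970684 to 54994626, Myl2 on chromosome 5 from 122100951 to 122113472 and Aldh3a1 on chromosome 11 from 61207537 to 61218421. By edgeR 605 genes were higher and 730 lower, with 140 and 137 beyond 2-fold. Without sham 28-day library 3 the counts were 366 and 465, and with library totals, which shift the median of all genes by -0.10, they were 298 and 1256.

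The 28-day vehicle libraries did not form one set. Hipk2, a nuclear kinase, stood between 4.98 and 21.8 CPM in the 4 sham 28-day libraries and in SCI vehicle 28-day libraries 1 to 4, and between 47.0 and 119 CPM in the other 24 libraries. The long transcript A630019I02Rik parted the same libraries, at 0.954 to 4.64 CPM against 15.3 to 530 CPM. No label names a batch for this division. With a term for these sets 423 genes were higher and 538 lower at 28 days, of which 868 were also called without it, and all 12 genes above kept their call. Only the 28-day vehicle libraries stand in both sets, so they alone set the size of the term. Here and below, SCI vehicle against sham at 28 days with the term therefore compares sham with SCI vehicle libraries 1 to 4 only. A call that ended with it may have ended for want of libraries.

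**Figure D2:**
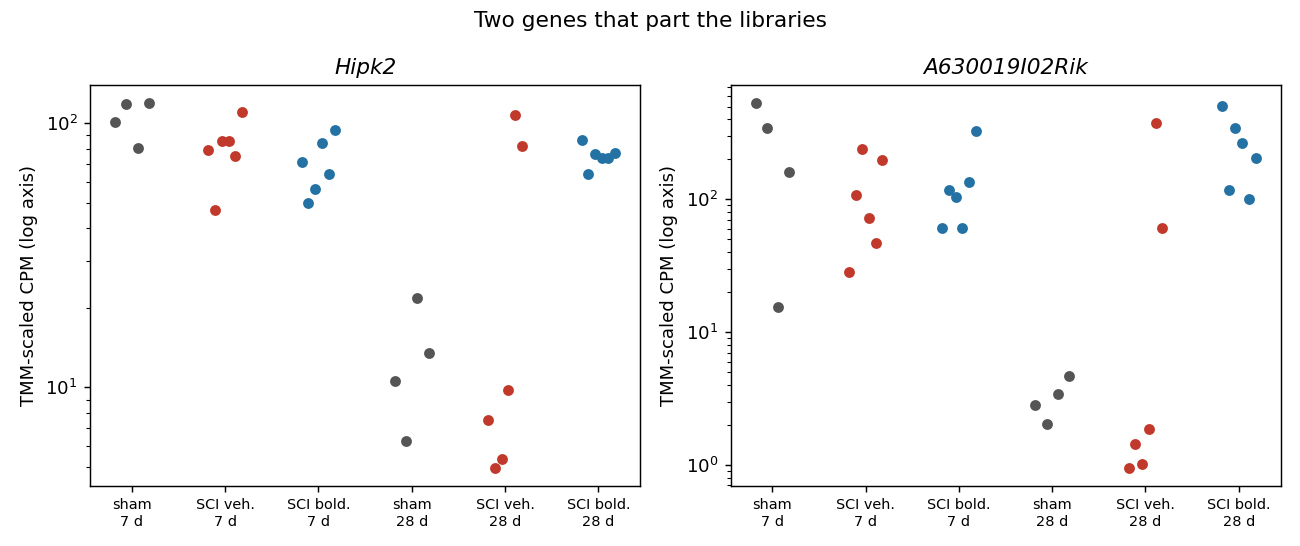
Levels of Hipk2 and A630019I02Rik in TMM-scaled CPM on a log axis, with 1 point per library in the 6 groups. All 4 sham and 4 of 6 SCI vehicle libraries of 28 days lie at or below 21.8 CPM for Hipk2, and the other 24 libraries at or above 47.0 CPM.

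By lists, 10 of 11 slow fibre genes fell at 28 days, 9 with the set term, and Atp2a2, the slow isoform of the sarcoplasmic calcium pump, fell from 344 ± 101 to 52.9 ± 4.18 CPM (camera 1.6e-15; adjusted p = 0.12 with an estimated correlation). Neuromuscular junction and denervation genes rose in 11 of 20, 7 with the set term, or 13 with 1 lower when adjusted over the list alone. Chrnb1 rose from 31.3 ± 5.98 to 72.3 ± 12.4 CPM and Myog, a muscle transcription factor, by 2.12 ± 0.34 (camera 3.2e-07; adjusted p = 0.12 with an estimated correlation). Fatty acid oxidation genes fell in 13 of 20, 10 with the set term, or 16 with 1 higher when adjusted over the list alone, led by Lpl (-1.61 ± 0.22) and Hadh (-0.69 ± 0.11), with a camera adjusted p of 1.2e-10 (adjusted p = 0.25 with an estimated correlation). OXPHOS genes fell in 16 of 45, 10 with the set term, or 32 when adjusted over the list alone and 35 with library totals, led by Uqcrq (-0.49 ± 0.09) and Sdhb (-0.55 ± 0.10), with a camera adjusted p of 1.5e-16 (adjusted p = 0.25 with an estimated correlation). Ribosomal protein genes rose in 15 of 48, 17 with the set term, or 26 when adjusted over the list alone, led by Rps4x (0.41 ± 0.07), and only 1 rose with library totals (camera 1.7e-16; adjusted p = 0.25 with an estimated correlation). Glucocorticoid response genes rose in 3 of 11, 2 with the set term, or 5 when adjusted over the list alone, with Zbtb16 at 1.39 ± 0.29 and Fkbp5 at 1.40 ± 0.34 (camera 2.9e-04; adjusted p = 0.25 with an estimated correlation). Developmental muscle genes rose in 3 of 8, 2 with the set term, or 5 when adjusted over the list alone, and Actc1, which was lower at 7 days, rose from 143 ± 90.4 to 541 ± 253 CPM (camera 0.020; adjusted p = 0.25 with an estimated correlation). In the fast fibre list the light chain Mylpf rose (0.76 ± 0.19) and Myh2, the heavy chain of oxidative fast fibres, fell (-2.08 ± 0.41), with 5 higher and 1 lower of 13 when adjusted over the list alone (camera 8.3e-04; adjusted p = 0.37 with an estimated correlation). Actn3 (0.73) was also called, but not without sham library 2, 3 or 4 (adjusted p 0.070, 0.095 and 0.052). Endothelial Kdr (-1.21 ± 0.20) and Cdh5 (-0.63 ± 0.14) and the matrix collagens Col4a1 (-0.97 ± 0.14) and Col4a2 (-0.99 ± 0.14) fell with and without the set term. For endothelial markers camera gave 0.0015 (adjusted p = 0.28 with an estimated correlation), and for matrix genes 0.16. Circadian genes rose in 4 and fell in 3 of 15 (camera 0.65), or 3 and 3 with the set term and 2 and 4 with library totals. By fry the adjusted p was 3.4e-04 for slow fibre, 0.0010 for junction, 0.0061 for fatty acid oxidation and 0.0075 for OXPHOS genes. It was 0.015 for ribosomal protein and for glucocorticoid response genes, 0.025 for developmental muscle and 0.019 for endothelial genes. Fast fibre (0.078), matrix (0.38) and proteasome genes (0.55) did not pass fry. Panx1, higher at 7 days, was lower at 28 days (3.94 ± 1.25 against 9.14 ± 2.03 CPM, adjusted p 0.027), a call that ended with the set term (0.080), with voom and quality weights (0.055), and without sham library 2 or 4 or SCI vehicle library 1 or 5 (0.11, 0.057, 0.057 and 0.057). Its list had a camera adjusted p of 0.037, or 0.063 with the set term (adjusted p = 0.25 with an estimated correlation for the first), with 3 of 9 lower when adjusted over the list alone. By fry this list passed as lower, with an adjusted p of 0.0044. The proteasome had 1 of 31 genes called, and its median of 0.08 became -0.01 with library totals (camera 0.0087; adjusted p = 0.82 with an estimated correlation).

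**Figure D3:**
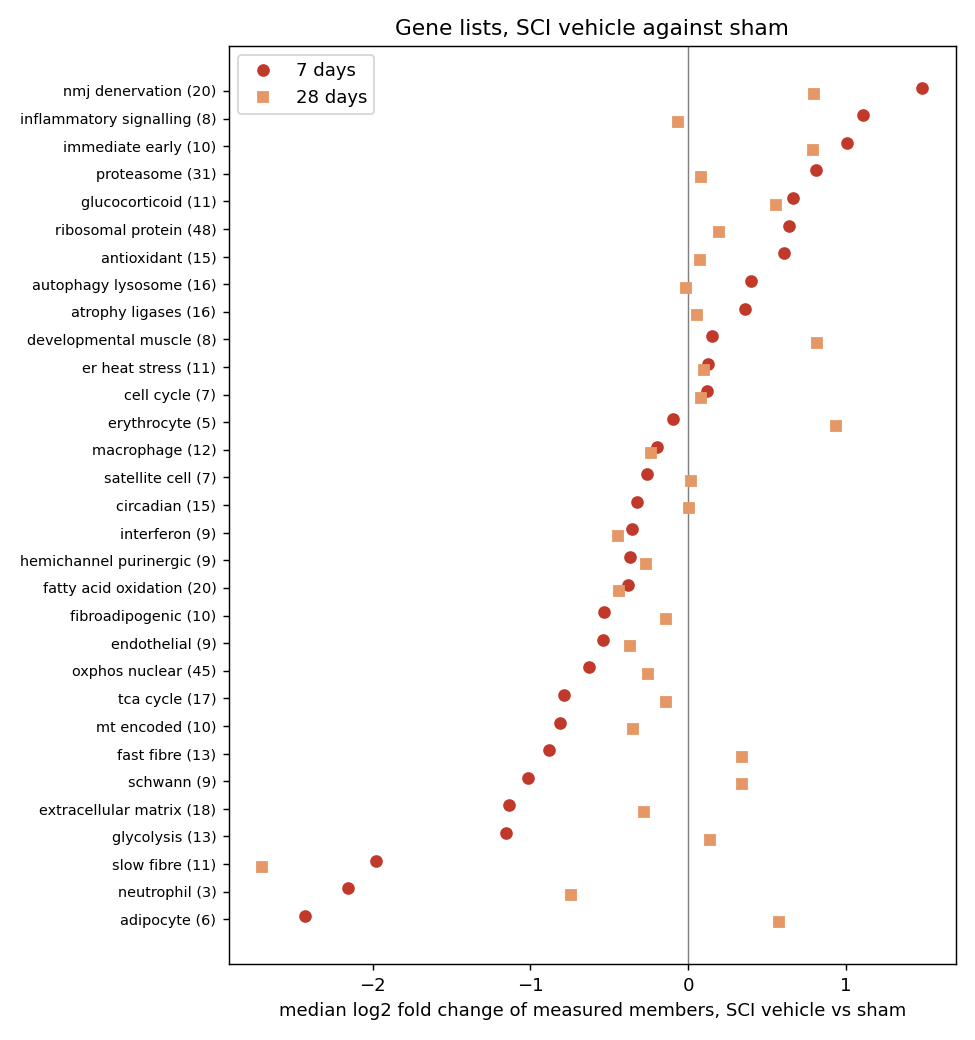
Median log2 fold change of the measured members of each list with at least 3 of them, SCI vehicle against sham, on the horizontal axis, with circles for 7 days, squares for 28 days and the number of members in brackets. The proteasome stood at 0.81 at 7 days and 0.08 at 28 days, which became -0.01 with library totals, the slow fibre list at -1.98 and -2.70, and the fatty acid oxidation median of -0.38 at 7 days became 0.01 with library totals, a change of sign also seen for macrophage, satellite cell, erythrocyte, hemichannel, interferon and circadian lists at 7 days and for ubiquitin ligase, satellite cell, antioxidant, circadian and cell cycle lists at 28 days.

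The SCI effect itself differed between 7 and 28 days. Actc1 rose relative to sham from one day to the other by 7.21 ± 0.67 (log2, SE; adjusted p 1.1e-08), Cyp2e1 by 4.22 ± 0.96 and Mybph, a myosin-binding protein gene that overlaps Adora1, by 3.49 ± 0.57. Myh7 (-4.86 ± 0.84), Mhrt (-4.52 ± 0.79) and Csf2rb2, a cytokine receptor subunit (-3.95 ± 0.94), fell, the last not with voom and quality weights (adjusted p 0.057). Proteasome genes fell in 30 of 31, with Psmd2 at -1.39 ± 0.16 (camera 5.7e-21; adjusted p = 0.22 with an estimated correlation). Glycolysis genes rose in 12 of 13, or 13 when adjusted over the list alone, with Pgk1 at 1.78 ± 0.17 (camera 4.0e-13; adjusted p = 0.18 with an estimated correlation), and fast fibre genes in 11 of 13, with Mylpf at 2.12 ± 0.27 (camera 2.9e-10; adjusted p = 0.18 with an estimated correlation). Of 18 matrix genes 10 rose, or 11 when adjusted over the list alone and 4 with library totals (median 0.93 and then 0.43), with Col1a1 at 1.60 ± 0.36 (camera 2.0e-05; adjusted p = 0.31 with an estimated correlation). OXPHOS genes rose in 26 of 45, or 32 when adjusted over the list alone, with Ndufs1 at 0.98 ± 0.12, but with library totals 3 rose and 8 fell and their median of 0.41 became -0.07 (camera 6.2e-14; adjusted p = 0.31 with an estimated correlation). By fry the adjusted p was 1.5e-04 for proteasome, 1.6e-05 for glycolysis and for fast fibre, 0.0021 for matrix and 7.5e-04 for OXPHOS genes. Nfkb2 (-3.37 ± 0.41) and Relb (-2.48 ± 0.35) fell, as did Panx1 (-3.19 ± 0.48). The test called 1736 genes higher and 1843 lower, or 533 and 6294 with library totals, which shift the median of all genes by -0.46. With the set term, where the 28-day SCI effect rests on SCI vehicle libraries 1 to 4 only, it called 1514 and 1619. Of these 2967 were called without it too. Of the genes called on both days 316 were higher and 510 lower on both, where 130 and 168 would be expected by chance, and 39 and 46 changed sides, where 157 and 140 would be. The days share no library.

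Boldine against vehicle at 7 days moved few genes past the test. Pxdn, a peroxidase that cross-links collagen IV, rose from 14.5 ± 2.61 CPM in SCI vehicle to 24.5 ± 5.93 CPM in SCI boldine (n = 6 each), a log2 fold change of 0.76 ± 0.13 (SE, adjusted p 0.018). Tfdp2, a partner of E2F factors, fell from 80.3 ± 6.81 to 58.5 ± 7.09 CPM (-0.46 ± 0.09, adjusted p 0.046). Called outside the naming rule and chosen after their values were seen, the receptor Gpr157 (-0.70 ± 0.12), the phosphodiesterase Enpp4 (-0.37 ± 0.07) and 2310015D24Rik (-0.92 ± 0.18) fell. In mm10, Pxdn lies on chromosome 12 from 29937608 to 30017658 and Tfdp2 on chromosome 9 from 96196275 to 96323646. Thus 1 gene was higher and 4 were lower by edgeR, with 1434 at an unadjusted p under 0.05 where 748 would be expected by chance. DESeq2 called 32 and 56 and voom with quality weights 3 and 1, and a fit of the 12 libraries alone called none, with 1012 at an unadjusted p under 0.05. Single libraries decided the count. Without SCI vehicle library 2 it was 30 and 38, without 6 it was 10 and 23, without 4 it was 6 and 5, without 1 it was 1 and 1, without 5 it was 0 and 1, and without 3 it was 0 and 0. Without SCI boldine libraries 1 to 6 in turn it was 3 and 3, 2 and 5, 0 and 3, 1 and 1, 0 and 0, and 5 and 5. The Pxdn call ended without vehicle library 3 or 5 or boldine library 3 or 5 (adjusted p 0.081, 0.056, 0.075 and 0.063), and that of Gpr157 without vehicle library 3 or boldine library 5 (0.057 and 0.063). Tfdp2 lost its call without vehicle library 1, 3 or 5 or boldine library 1, 4 or 5 (0.11, 0.12, 0.060, 0.057, 0.091 and 0.076). The same libraries ended the call of 2310015D24Rik (0.11, 0.057, 0.056, 0.057, 0.091 and 0.076), as did boldine library 6 (0.072), and that of Enpp4 (0.11, 0.12, 0.10, 0.068, 0.091 and 0.076), as did boldine library 3 (0.16).

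No list member passed the test over all genes for boldine at 7 days by edgeR. Adjusted over the list alone, 5 of 5 erythrocyte genes were higher, such as the globins Hbb-bt (0.89) and Hba-a2 (0.95), and 4 of 6 adipocyte genes, such as Plin1 (1.44) and Adipoq (1.35). So was the junction gene Chrnd (0.73), and glycolytic Pkm was lower (-0.29). By camera the slow fibre list had a median of 0.49 (1.3e-04; adjusted p = 0.59 with an estimated correlation), the junction list 0.26 (1.3e-04; adjusted p = 0.42 with an estimated correlation) and macrophage markers 0.32 (1.3e-04; adjusted p = 0.52 with an estimated correlation). Extracellular matrix had 0.25 (1.8e-04; adjusted p = 0.59 with an estimated correlation), fatty acid oxidation 0.17 (3.9e-04; adjusted p = 0.59 with an estimated correlation) and erythrocyte genes 0.80 (3.2e-04; adjusted p = 0.52 with an estimated correlation). Glycolysis had -0.29 (1.3e-04; adjusted p = 0.59 with an estimated correlation) and the proteasome -0.08 (0.0026; adjusted p = 0.87 with an estimated correlation). Adipocyte markers had 1.40 (0.0053; adjusted p = 0.59 with an estimated correlation), fibro-adipogenic markers 0.24 (0.0053; adjusted p = 0.59 with an estimated correlation) and ribosomal proteins 0.04 (0.013; adjusted p = 0.88 with an estimated correlation), calls that ended without SCI vehicle library 2 for the first 2 lists (0.061 and 0.17) and without 3 for the last (0.32), among others. SCI vehicle library 3 stood apart in the slow fibre list, at a mean of 2.89 log2 CPM against 4.51 to 5.77 in the other vehicle libraries, and without it the median on voom values went from 0.74 to 0.30 (camera 0.021). Glycolysis no longer passed camera without that library (0.058), nor did the matrix list without SCI vehicle library 2 (0.12) or the proteasome without SCI vehicle library 1, 2 or 5 or SCI boldine library 1 or 6 (0.40, 0.82, 0.066, 0.33 and 0.068). By fry, which asks whether members move one way on balance, none of these 11 lists passed, with adjusted p from 0.21 for the junction list to 0.77 for ribosomal proteins. The cell cycle list passed fry (0.035), with a median of 0.34 (camera 0.0031; adjusted p = 0.21 with an estimated correlation), and the replication gene Mcm4 (0.61) was higher when adjusted over the list alone. The hemichannel and purinergic list had a median of 0.08 (camera 0.98), and P2rx6 within it was lower when adjusted over the list alone (-0.41).

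At 28 days boldine against vehicle also gave small differences. Fryl rose from 20.4 ± 2.59 to 30.0 ± 3.79 CPM (0.56 ± 0.10), and Smcr8, part of a complex that regulates autophagy, from 29.4 ± 5.21 to 40.9 ± 1.92 CPM (0.48 ± 0.09). Lrp10, a lipoprotein receptor family member, fell from 33.8 ± 2.82 to 26.7 ± 0.480 CPM (-0.34 ± 0.06; adjusted p 0.031 for each of the 3). Smcr8 overlaps Shmt1 and Lrp10 overlaps Gm10366. These were the calls of edgeR, 2 higher and 1 lower, with 1430 at an unadjusted p under 0.05, while DESeq2 called 38 and 6 and voom with quality weights 233 and 101. All 6 boldine libraries but only SCI vehicle libraries 5 and 6 stood in the Hipk2-high set. The description codes of SCI vehicle libraries 5 and 6 follow that of SCI boldine library 6 under 1 letter, and whether vehicle 5 and 6 carry the right treatment label was not tested, so each 28-day value of boldine against vehicle rests on the labels as given. The set term is estimated from the 28-day vehicle libraries alone. A fit with it therefore compares the boldine libraries with SCI vehicle libraries 5 and 6 only. In that fit edgeR called none, with 536 at an unadjusted p under 0.05. The folds were 0.42 for Fryl, 0.25 for Smcr8 and -0.24 for Lrp10. Counting SCI boldine library 6 as vehicle also gave none, with 1275 at an unadjusted p under 0.05. Without SCI vehicle library 5 the counts were 125 and 43, without library 6 they were 47 and 9, and without library 1, 2, 3 or 4 they were 0 and 0. Leaving out boldine library 1, 2 or 3 gave 1 and 0, with Fryl still called and Smcr8 (0.071, 0.10 and 0.12) and Lrp10 (0.071, 0.11 and 0.12) not, and leaving out 4, 5 or 6 gave 0 and 0.

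Extracellular matrix genes stood lower with boldine at 28 days, with a median of -0.36 that was -0.31 with the set term (camera 1.7e-09 and 4.4e-05; adjusted p = 0.33 with an estimated correlation for the first, and 0.11 by fry). Here and below, values with the set term compare boldine with SCI vehicle libraries 5 and 6 only, whose treatment label was not tested. No member passed over all genes by edgeR, and 4 of 18 were lower when adjusted over the list alone, among them Tnc (-1.54 ± 0.43), a matrix glycoprotein, and the collagen Col1a2 (-0.71 ± 0.20), or 0 with the set term. Of 15 circadian genes 1 was higher and 3 were lower when adjusted over the list alone (camera 0.43), and 0 with the set term. Erythrocyte genes had a median of -0.32 (camera 0.043; adjusted p = 0.86 with an estimated correlation) or -0.62 with the set term (1.8e-04), endothelial markers -0.13 (0.043; adjusted p = 0.86 with an estimated correlation) or -0.05 (0.64) and fibro-adipogenic markers -0.10 (0.21) or -0.19 (0.0096), while macrophage markers had 0.33 (0.11) and adipocyte markers 0.88 (0.059). Fatty acid oxidation genes had 0.11 (0.043; adjusted p = 0.86 with an estimated correlation) or 0.17 with the set term (0.0012). OXPHOS (0.05, 0.018), ribosomal protein (0.04, 0.014) and glucocorticoid response genes (0.23, 0.027) passed camera with the set term only. Without it they had 0.02 (0.51), -0.04 (0.13) and 0.23 (0.19), so the ribosomal protein median changed sign. With an estimated correlation and no set term their adjusted p was 0.94, 0.91 and 0.86. The 3 calls at 0.043 ended when single libraries were left out, 6 or 7 of the 12 in turn. The heat shock genes Hspa1a (-1.82) and Hspa1b (-1.83), near-identical copies whose reads are hard to tell apart, were lower when adjusted over the list alone, at -0.42 and -0.54 with the set term. Hspa1a stood at 10.5 ± 16.3 CPM in SCI vehicle, where library 4 stood apart in their list at a mean of 5.58 log2 CPM against 4.66 to 4.90 in the other vehicle and 4.51 to 4.86 in the boldine libraries. Immediate early genes had a median of -0.40 (camera 0.011; adjusted p = 0.86 with an estimated correlation), which did not pass without SCI boldine library 1 (0.088). Satellite cell markers alone passed fry (0.0072), with a median of -0.18 (camera 0.070) that was -0.04 with the set term (camera 0.62) and 1 of 7 lower when adjusted over the list alone. The hemichannel and purinergic list had -0.14 (camera 0.21).

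Boldine-treated injured muscle was compared with sham to see how far it stood from uninjured muscle. At 7 days Krt18 rose by 6.93 ± 0.64, Sln by 6.62 ± 0.55 and Ces2c by 6.27 ± 0.53. Actc1 (-4.86 ± 0.47), Bdh1 (-4.43 ± 0.42) and Ostn (-4.18 ± 0.29) fell. Proteasome genes rose in 31 of 31 and ribosomal protein genes in 47 of 48, while 43 of 45 OXPHOS genes and 13 of 13 glycolysis genes fell. In all 3244 genes were higher and 3370 lower, or 7787 and 1187 with library totals, which shift the median of all genes by 0.44. At 28 days Sln rose by 6.92 ± 0.56, to 128 ± 70.8 CPM, and Aldh3a1 by 5.12 ± 0.74, while Myh7 (-6.34 ± 0.63) and Myl2 (-5.62 ± 0.54) fell. Here 1314 genes were higher and 1399 lower, or 842 and 1999 with library totals, which shift the median of all genes by -0.10. All boldine and no sham library of 28 days stood in the Hipk2-high set. With the set term, which then rests on the vehicle libraries, 90 and 129 genes were called, 198 of them also called without it. Sln (6.52, adjusted p 3.9e-05) and Aldh3a1 (5.13, 0.0087) kept their calls, and Cyp2e1 (3.30 ± 1.09, 0.12), Mhrt (-5.26 ± 2.61, 0.36), Myh7 (-5.06 ± 1.60, 0.11) and Myl2 (-5.08 ± 1.74, 0.14) did not. Their folds stayed large and their errors widened, so the lost calls do not assign these changes to the sets.

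The boldine effect differed between days for 1 gene. Tfdp2 was 0.78 ± 0.13 higher in its boldine effect at 28 days than at 7 days (adjusted p 0.012), with 90.7 ± 10.2 CPM in SCI boldine against 72.7 ± 7.82 CPM in SCI vehicle at 28 days. The call ended with the set term, with the replicate block and with library totals (adjusted p 0.51, 0.076 and 0.18). With the set term the 28-day boldine effect again rests on SCI vehicle libraries 5 and 6 only. Pxdn (-0.91), Marcks (-0.69) and Lrp10 (-0.42) had the smallest p-values in the other direction, each with an adjusted p of 0.12. By edgeR 1 gene was higher and 0 lower, with 1453 at an unadjusted p under 0.05, while DESeq2 called 20 and 14 and voom with quality weights 2 and 0. Without SCI vehicle 28-day library 5 the counts were 17 and 7, and without SCI boldine 28-day library 6 they were 2 and 0, and without SCI vehicle 7-day library 1 they were 1 and 1. Extracellular matrix genes had a median of -0.61 (camera 1.7e-12; adjusted p = 0.20 with an estimated correlation, and 0.033 by fry), with 8 of 18 lower when adjusted over the list alone and 0 with the set term (median -0.56, camera 1.1e-08). Erythrocyte genes had a median of -1.10 (camera 3.8e-05; adjusted p = 0.26 with an estimated correlation), or -1.47 with the set term (1.6e-07). Satellite cell markers had -0.23 (camera 0.042; adjusted p = 0.25 with an estimated correlation, and 0.0054 by fry), and the set term ended that camera call (-0.18, 0.39). It also ended those of cell cycle, heat stress and ribosomal protein genes (0.042, 0.042 and 0.0047, then 0.32, 0.39 and 0.90) and kept those of fibro-adipogenic, glucocorticoid response and immediate early genes (0.0047, 0.042 and 0.042, then 1.2e-04, 0.0075 and 0.030), none of which passed with an estimated correlation (adjusted p from 0.26 to 0.84).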

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

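The tests for exchanged labels, for a lower share of fibre RNA and with a term for the library sets were chosen after the result was seen. The SCI effect differed between days by a test of the difference itself, in 1736 genes higher and 1843 lower at 28 than at 7 days relative to sham. Of the genes named for it, Actc1 differed by 7.21, Cyp2e1 by 4.22, Mybph by 3.49, Myh7 by -4.86, Mhrt by -4.52 and Csf2rb2 by -3.95 on the log2 scale. The boldine effect differed between days in 1 gene, Tfdp2, by 0.78.

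Single libraries stood far from the rest of their group in 6 of 100 tests, where about 1 in 20, or 5, would be expected by chance. The gap to the nearest library as a share of the group's range was 0.85 for Perm1 in sham 7-day library 2 (118 CPM, the others 216 to 241), 0.851 for Ostn in sham 7-day library 4 (22.7 CPM, the others 44.5 to 50.1) and 1 for Cd101 in sham 7-day library 3 (0.0877 CPM, the others 0). It was 0.70 for Aif1l in SCI vehicle 28-day library 3 (5.38 CPM, the others up to 23.3) and 0.638 for Bdh1 in SCI boldine 7-day library 3 (4.88 CPM, the others 0.475 to 1.16). On the second principal component it was 0.833 for sham 28-day library 4.

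The 28-day libraries parted by Hipk2 and A630019I02Rik, and 8 of them, all 4 sham and SCI vehicle 1 to 4, stood low. A technical difference between library sets may account for this, since the differences across genes between low and high vehicle libraries of 28 days correlated with those between 28-day and 7-day sham (r 0.338 across genes, which are not independent), while the other 14 of 15 ways to divide the 6 vehicle libraries gave at most 0.177. An exchange of labels between vehicle and boldine libraries of 28 days, as the source of the sets, would need a boldine library in the low set, and there were 0. That count was known when the prediction was written. An exchange between SCI vehicle 5 or 6 and a boldine library, all of them high, would also leave 0 and is not excluded. The count also says nothing of a wrong label on SCI vehicle 5 and 6 alone, which was not tested. No label names a batch, so what the sets are stays open, and no biological explanation of them was tested.

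The differences between boldine and vehicle at 28 days could reflect those sets. Across genes the boldine fold changes correlated with 7-day minus 28-day sham at r 0.339, and at 0.0469 with the set term. The fit with the term compares boldine with SCI vehicle libraries 5 and 6 only. The SD of the fold changes was 0.29 without and 0.37 with the term and their median SE 0.145 and 0.204, so the calls ended with smaller folds for the called genes and a wider error. A boldine effect stays open, and so does one that is smaller than these errors.

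The 7-day SCI shift, with OXPHOS and glycolysis lower and proteasome and ribosomal proteins higher, is not likely to come from the scaling of the libraries alone, since OXPHOS kept a median of -0.25 with library totals, glycolysis -0.77, the proteasome 1.22 and ribosomal proteins 1.04. A lower share of muscle fibre RNA among other cell types would raise the markers of every other type, yet endothelial markers had a median of -0.54 (SE of members 0.21), fibro-adipogenic markers -0.54, adipocyte markers -2.43 and macrophage markers -0.20. With library totals these were -0.15, -0.15, -2.06 and 0.19. A change within the fibres, and a change in single cell types, stay open as untested hypotheses.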

How the results depend on the processing

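The term for the library sets was chosen after seeing the data, and all other alternatives before. Counts over both SCI comparisons with sham at 7 days stayed within 1.5 times under every alternative run but library totals, which gave 7107 higher and 1362 lower for vehicle and 7787 and 1187 for boldine, since TMM factors of 7-day SCI libraries lay above those of the others. SCI vehicle at 28 days gave 298 and 1256 with library totals, 942 higher with the compared groups alone, a fit on fewer libraries, and 1115 lower with voom and quality weights. For boldine against sham at 28 days library totals gave 842 higher, and the set term 90 and 129, where treatment and set coincide. The difference of SCI effects gave 533 and 6294 with library totals. For boldine against vehicle at 7 days, higher and lower counts were 32 and 56 with DESeq2, 3 and 1 with voom, 16 and 8 without the filter, 0 and 0 with the compared groups alone, and 8 and 11 with the set term, robust dispersions gave 2 higher, and library totals 1 lower. At 28 days they were 38 and 6 with DESeq2, 233 and 101 with voom, 4 and 0 with library totals, 1 and 0 without the filter, and 0 and 0 with the compared groups alone, with library 6 as vehicle and with the set term. The difference of boldine effects gave 20 and 14 with DESeq2, 2 higher with voom, 3 with library 6 as vehicle, and 0 with library totals and with the set term. Where no reason is given the cause was not tested. Leaving out 1 library gave 2887 to 3404 higher and 3000 to 3342 lower for SCI at 7 days, 366 to 609 and 465 to 700 at 28 days, 0 to 30 and 0 to 38 for boldine against vehicle at 7 days, and 0 to 125 and 0 to 43 at 28 days. It gave 2960 to 3357 and 3039 to 3330 for boldine against sham at 7 days, 1012 to 1266 and 1009 to 1339 at 28 days, 1491 to 1870 and 1631 to 2081 for the difference of SCI effects, and 1 to 17 and 0 to 7 for that of boldine effects.

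Replicate numbers did not pair the libraries, as 3 of 72 same-number pairs correlated above 0.1 (median 0.0024) and 6 of 32 libraries fitted best with their own number. With the replicate block boldine against vehicle gave 2 and 2 at 7 days, 0 and 0 at 28 days, and the difference of boldine effects 0 higher, while SCI gave 3162 and 3392 at 7 days and 576 and 673 at 28 days.

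P2rx6 at 7 days turned to 0.0164 and Per3 in the difference of SCI effects to -0.0181 with library totals, and the mean correlation of SCI and boldine effects at 7 days turned to 0.039 with genes of at least 5 CPM. For ribosomal proteins in the difference of boldine effects the set term reversed the direction of camera (adjusted p 0.90). Their median stayed below 0, at -0.08 without the term and -0.0046 on voom values with it. Calls of named genes ended in 36 cases with library totals, 25 with the set term, 16 with voom, 13 with the block, 10 with the compared groups alone, 9 without the filter, 4 with library 6 as vehicle, 3 with robust dispersions and 204 with 1 library left out. Of the camera calls outside boldine against sham, 72 of 72 ended with an estimated correlation. Camera was not run for DESeq2 and robust dispersions. Depth limits genes such as Cd101, with 1 count in sham.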

Other observations

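The term for the library sets and the relations of the proteasome to junction and fast fibre genes were chosen after the result was seen. Between 7 and 28 days after injury, relative to sham, tricarboxylic acid cycle genes rose in 15 of 17, with 1 lower when adjusted over the list alone and 5 higher and 2 lower with library totals (median 0.59 and then 0.11), led by Idh3a (1.39 ± 0.16; camera 5.2e-12; adjusted p = 0.22 with an estimated correlation), and ribosomal protein genes fell in 33 of 48, or 38 when adjusted over the list alone, led by Rpl3 (-2.09 ± 0.26; camera 3.1e-16; adjusted p = 0.31 with an estimated correlation). Autophagy and lysosome genes fell in 9 of 16, or 14 with library totals, with Map1lc3a at -1.13 ± 0.12 (camera 3.0e-04; adjusted p = 0.18 with an estimated correlation), while Ctsb rose by 0.71, a call that ended with library totals. Fibro-adipogenic markers rose in 6 of 10, or 8 when adjusted over the list alone, 4 with the set term and 1 with library totals (median 0.73 and with totals 0.25), with Cd248 at 1.80 ± 0.34 (camera 9.5e-04; adjusted p = 0.35 with an estimated correlation). Adipocyte markers rose in 3 of 6, or 5 when adjusted over the list alone, with Adipoq at 3.25 ± 0.87 (camera 0.027, or 0.068 with the set term; adjusted p = 0.53 with an estimated correlation for the first). A part of this rise lay in sham. The means of the adipocyte list ran from 1.66 to 3.63 log2 CPM in 7-day sham and from -0.02 to 2.42 in 28-day sham. In SCI vehicle they ran from -0.47 to 0.81 at 7 days and from -0.81 to 2.32 at 28 days. At 28 days erythrocyte genes had a median of 0.94 in SCI vehicle against sham, with 0 of 5 called by edgeR and 3 when adjusted over the list alone (camera 0.0049; adjusted p = 0.37 with an estimated correlation).

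Among the 12 SCI libraries of 7 days it was asked whether fibre gene loss and proteasome expression move together. The values show such a relation for fast fibre genes only. The prediction concerned OXPHOS, whose list mean had Pearson r -0.436 with that of the proteasome (permutation p 0.142, Spearman rho -0.301 with permutation p 0.347, and r -0.415 without the 2 farthest libraries), which left the question undecided. Of the 3 relations computed, fast fibre genes gave r -0.851 (permutation p 5.8e-04, adjusted 0.00174; rho -0.811 with permutation p 0.00188; r -0.824 without the 2 farthest libraries). Within vehicle and within boldine r was -0.414 (exact p 0.394) and -0.528 (0.319) for OXPHOS, -0.904 (0.0444) and -0.875 (0.0222) for fast fibre genes, and 0.823 (0.0333) and 0.747 (0.0917) for junction genes. Over both groups junction genes gave r 0.551 (permutation p 0.0559, adjusted 0.0838; rho 0.517 with permutation p 0.0883; r 0.706 without the 2 farthest libraries). No correlation was computed for slow fibre genes, whose list means did not run one way. In SCI vehicle, library 2 was highest in proteasome and slow fibre means (7.78 and 5.77 log2 CPM) and library 3 lowest in both (7.08 and 2.89). In SCI boldine, library 5 was highest in proteasome and lowest in slow fibre (7.60 and 4.88), and library 1 the reverse (7.13 and 5.80).

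Whether boldine changed genes against the SCI effect was tested with vehicle libraries divided, so that no library served both differences. The mean correlation across genes was -0.0072 at 7 days, from -0.296 to 0.382 over 20 divisions, and 0.147 at 28 days, from 0.0230 to 0.288. With the vehicle group shared, the covariance at 7 days was -0.0225 in the data and -0.0214 in simulations with no effect. With genes of at least 5 CPM these were -0.0030 and -0.0091. At 28 days over all genes they were -0.0011 and -0.0238. At 7 days 11 of 20 divisions were negative, so no direction is given. At 28 days both differences hold a part of the library sets, which the vehicle group straddles, and no value with the set term was computed, so an opposite direction is not excluded there.

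With libraries divided at random, 1 of 100 splits, the real one, gave as many genes as SCI vehicle against sham at 7 days (6669, highest other 3738) and at 28 days (1335, highest other 274). That is the smallest share that 100 splits can give, so chance is unlikely for both counts. The same held for boldine against sham at 7 days (6614, highest other 3136) and 28 days (2713, highest other 529). For the difference of SCI effects 2 of 100 splits gave at least the 3579 genes called, a share under 0.05, but 1 of these, which exchanged 3 libraries, called more, 4455. For boldine against vehicle at 7 days 17 of 100 splits gave at least the 5 genes called, so chance is not excluded, and the highest other, 1778, points to a structure among the 7-day SCI libraries. At 28 days 3 of 100 did for the 3 genes called (highest other 78), but the splits as large were those with all 4 low-set libraries in the vehicle group. Such splits also keep most treatment labels, so that share cannot tell the sets from boldine. With the set term, which compares boldine with SCI vehicle libraries 5 and 6 only, 0 genes were called by edgeR (536 at an unadjusted p under 0.05). The highest other there is again many times the real count and points to that structure. For the difference of boldine effects 8 of 100 splits gave at least the 1 gene called (highest other 578), so chance is not excluded.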
